A study of Mus musculus with 9 samples.

How the data were processed

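RNA was measured in single cells from 9 mouse liver samples, 3 in each of 3 groups. All animals carried the Pdcd1-/- genotype, in which the gene for the inhibitory receptor PD-1 is disrupted. Per the labels' protocols, livers were dissociated with a Miltenyi kit, red blood cells were lysed, and CD45+ cells (leukocytes) were enriched with magnetic beads. Cells were loaded on a 10x Genomics Chromium controller with 5′ v2 chemistry, which reads the 5′ end of each transcript and marks each molecule with a unique molecular identifier (UMI). For each library the authors deposited a count matrix in UMIs per gene and barcode, with lists of its barcodes and of 27998 genes. The submitters' processing notes name Cell Ranger 3.0.2, Seurat 3.0.1 and the mouse build mm10, without the role of each. The counts are whole numbers, and no cell annotation was used here. Gene identifiers were those of the files. Coordinates came from GENCODE vM21 on GRCm38 (mm10), in which all 264 named genes were found by Ensembl identifier, and 56 symbols that stand on more than 1 identifier were kept as separate entries.

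Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Doublets were called in each library from simulated sums of barcode pairs (1500 variable genes, 20 principal components). The barcodes with the highest scores were called at a rate of 0.8% per 1000 kept barcodes, so 1.10% to 3.74% were removed in 8 libraries. In replicate 2 of the 9D9 + epacadostat group the simulated doublets could not be told from the barcodes and 0 were called. Kept barcodes were clustered by the Leiden method (leidenalg 0.10.2, igraph 0.11.9, resolution 1, 2000 variable genes, 30 principal components, 20 neighbours) with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0. A cluster received the name of the cell type whose marker list, fixed before the data were examined, had the highest mean score, from 0 for the lowest cluster to 1 for the highest. A type with more of its markers among the cluster's 10 leading genes and a score within 0.1 of the highest took precedence. A name needed a score of 0.7 and 3 detected markers. The numbers in this naming rule were set after the data were seen. Among the fixed markers 12 were absent from the files. Clusters with over 25% called doublets (clusters 17, 20 and 23), with over 90% of barcodes from 1 library (clusters 1 and 26) or led by genes of other types (cluster 22) stayed unnamed. These unnamed clusters held 6.44% ± 2.40 (SD, n = 3) of kept barcodes in vehicle libraries, 3.15% ± 2.00 (SD, n = 3) under anti-4-1BB, and 11.9%, 94.7% and 3.49% in replicates 1, 2 and 3 of the 9D9 + epacadostat group. Class names are therefore rebuilt from markers and mean "X-like" throughout.

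UMI counts were summed per library and class, because cells are not replicates, and a library entered a class with at least 20 barcodes. Groups were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood fit of all groups together, 2-sided test) at a Benjamini-Hochberg adjusted p under 0.05. "Rose" and "fell" refer to genes past that threshold. Log2 fold changes carry standard errors derived from the F statistic, and levels are CPM, counts scaled to a fixed library total, with SD over libraries. The tests, the samples in each fit, 21 gene lists, the cell markers and the rule for named genes were fixed before the data were examined. That rule took Pdcd1, Ctla4, Tnfrsf9 and Ido1, then the 4 rising and 4 falling genes with the largest fold change among called genes of at least median abundance whose groups did not overlap (3 and 3 between the treatments and in minor classes), and from each list the 2 members with the smallest p, or up to 4 where over 5 passed. Genes of immunoglobulin and T cell receptor segments, mitochondrial and ribosomal protein genes, sex-linked genes, unnamed gene models, hepatocyte and erythroid list members and markers of other classes were excluded from the fold change part. Chance separates the libraries of 3 against 3 fully in 10% of genes. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with the correlation estimated, and with fry, adjusted over all 251 tests. List members were also counted with p adjusted over the list alone.

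Class shares are percentages of kept barcodes other than called doublets. They were compared by 2-sided exact permutation tests over 1680 arrangements for 3 groups, 84 for both treatments against vehicle, and 20 for pairs of groups, with adjustment over classes. A pair of groups of 3 cannot give a p below 0.1. Shares of single libraries carry 95% Clopper-Pearson intervals, and a count of 0 allows up to 3 barcodes. These cover counting error only. In simulated data with 10494 genes drawn from the CD8 T-like sums, the test of anti-4-1BB against vehicle recovered 97% of 4-fold and 69% of 2-fold changes with 4.60% false calls. It recovered 98% and 68% over all CD45+ cells (12267 genes), 98% and 65% in monocytes and macrophages (9540 genes, 8.43% false calls), 90.4% and 37.4% in CD4 T-like sums (5061 genes, 8.27% false calls) and 88.2% and 34.7% in Kupffer-like sums (5281 genes, 4.13% false calls).

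Alternatives were DESeq2 1.42.0, RLE factors in edgeR, no filter on low counts, the replicate number as a block, fits of only the 2 groups compared, stricter barcode filters (1000 UMIs and 500 genes, or 5% mitochondrial UMIs), kept doublets, finer clusters (resolution 2), T cells split by Cd8 and Cd4 UMIs, other denominators for shares, and each library left out in turn. The most RNA that CD8 T-like cells could bring to Kupffer-like sums was taken from their Nkg7, as if all of it came from such cells, and likewise for monocytes and macrophages, B-like cells and CD4 T-like cells (with Lyz2 for RNA of monocytes and macrophages). These bounds, thinned counts, CD8 T-like sums without the cycling cluster, and minor classes and lists without replicate 2 of the 9D9 + epacadostat group were added after the data were seen. TMM and RLE factors and DESeq2 moved the median fold change of all genes in a comparison to no more than 0.041 from 0 (log2). NK-like cells were too few under treatment for a comparison of genes.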

Results

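Liver leukocytes of Pdcd1-/- mice were profiled as single cells under 3 treatments, with 3 libraries each. One group received isotype antibody and vehicle. Another received an agonistic antibody against 4-1BB (the product of Tnfrsf9, a costimulatory receptor of activated T cells). The last received 9D9, an antibody against CTLA-4, together with epacadostat, an inhibitor of the tryptophan-degrading enzyme IDO1. The series asks which T cells and monocyte-derived myeloid cells take part in hepatitis after immunotherapy. The labels number the replicates without saying what sets them apart, so p-values measure the spread between these samples, which may be technical in part. No libraries were copies of each other, with at most 2.32% of genes at equal counts in any pair.

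Depth differed with the groups. Vehicle libraries held 15089114, 13050728 and 13075282 UMIs, anti-4-1BB libraries 33632054, 32698804 and 17186539, and 9D9 + epacadostat libraries 6027136, 20260381 and 20238907. Median UMIs per kept barcode were 3237, 2635 and 3350.5 in vehicle libraries, 6269, 6000 and 6196 under anti-4-1BB, and 2858.5, 642 and 3818 under 9D9 + epacadostat. Replicate 2 of the 9D9 + epacadostat group stood apart. Its matrix listed 41083 barcodes, where the other libraries listed 1462 to 4698, with a median of 415 UMIs before filtering. Of its 7818 kept barcodes 94.7% fell in unnamed clusters, so it contributed only 11 CD8 T-like, 2 CD4 T-like and 4 B-like barcodes. It entered the comparisons of all CD45+ cells, Kupffer-like cells, neutrophils and type 1 dendritic cells. In the other classes compared for 9D9 + epacadostat that group had n = 2, and NK-like and NKT-like cells reached 20 barcodes in only 1 of its libraries and were not compared.

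Tnfrsf9, the target of the agonist (ENSMUSG00000028965, chromosome 4, 150914562 to 150946102, plus strand, GRCm38), rose in CD45+ cells under anti-4-1BB and, on weaker grounds, under 9D9 + epacadostat. Its level was 32.8, 29.1 and 34.7 CPM in vehicle libraries, 102, 117 and 127 CPM under anti-4-1BB, and 59.8, 40.4 and 76.3 CPM under 9D9 + epacadostat. The log2 fold changes against vehicle were 2.02 ± 0.17 (SE, n = 3 against 3, edgeR adjusted p = 0.000159) and 1.08 ± 0.17 (adjusted p = 0.0408). Ctla4, the target of 9D9 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832, plus strand), rose by 1.52 ± 0.29 under 9D9 + epacadostat (edgeR adjusted p = 0.0465), and its change under anti-4-1BB did not pass (0.65 ± 0.29, adjusted p = 0.0909). The 9D9 + epacadostat calls of Tnfrsf9 and Ctla4 were lost without any single vehicle library, without anti-4-1BB replicate 2 or 3, without 9D9 + epacadostat replicate 1 or 2, with the replicate block, in fits of only the 2 groups and under both stricter barcode filters. Pdcd1, the disrupted gene (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand), gave UMIs in every library, from 978 to 9616 over all CD45+ cells. The labels do not say which part of Pdcd1 is deleted, so UMIs read from the 5′ end check nothing about the genotype. Pdcd1 rose under anti-4-1BB (0.98 ± 0.36, edgeR adjusted p = 0.0476) and did not pass under 9D9 + epacadostat (1.23 ± 0.36, adjusted p = 0.0715). Ido1, the target of epacadostat (ENSMUSG00000031551, chromosome 8, 24584136 to 24597009, minus strand), had 3 to 16 UMIs per library, too few to compare.

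CD8 T-like cells made up most leukocytes under anti-4-1BB. They were 56.3% ± 4.15 (SD, n = 3) of kept barcodes there and 32.6% ± 6.05 (SD, n = 3) in vehicle libraries. In replicates 1 and 3 of the 9D9 + epacadostat group they were 48.1% (95% interval 45.4% to 50.8%) and 53.4% (51.8% to 55.0%). Monocyte and macrophage-like cells were 25.4% ± 1.25 under anti-4-1BB, 11.1% ± 5.62 in vehicle and 10.6% ± 5.61 (n = 2) in 9D9 + epacadostat without replicate 2. B-like cells were 21.3% ± 8.99, 1.22% ± 0.197 and 7.61% ± 2.19 in the same order of vehicle, anti-4-1BB and 9D9 + epacadostat. NK-like cells numbered 129, 65 and 109 barcodes in vehicle libraries and 1, 0 and 5 under anti-4-1BB, where a count of 0 of 4498 allows up to 0.0667%. They made up 0.539% ± 0.0246 of the 2 usable 9D9 + epacadostat libraries. CD4 T-like cells, all of a regulatory T-like cluster, were 3.12% ± 0.614, 1.83% ± 0.462 and 6.46% ± 0.929.

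Across 9 libraries and 14 classes no share passed the exact permutation test over 3 groups after adjustment. In that permutation test NK-like cells (p = 0.00714), B-like cells (p = 0.0143) and monocytes and macrophages (p = 0.0179) each had an adjusted p = 0.0833, and CD8 T-like cells had p = 0.225. In the exact test of both treatments against vehicle, B-like and NK-like cells had p = 0.0119 (adjusted p = 0.0833), with every treated library below every vehicle library. Exact tests of pairs of groups could not go below p = 0.1. Without replicate 2 of 9D9 + epacadostat the exact 3-group test gave p = 0.0393 for B-like cells (adjusted p = 0.13). That library held 4 B-like and 4 NK-like barcodes of 7818. Without it the exact test gave p = 0.00357 for CD4 T-like cells (adjusted p = 0.05, not under the threshold) and p = 0.0107 for CD8 T-like cells (adjusted p = 0.075). Without vehicle replicate 3, NK-like cells and nonclassical monocytes also had an adjusted p = 0.05. Every share depends on CD45 bead enrichment and, in that 1 library, on barcodes of low depth.

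**Figure D1:**
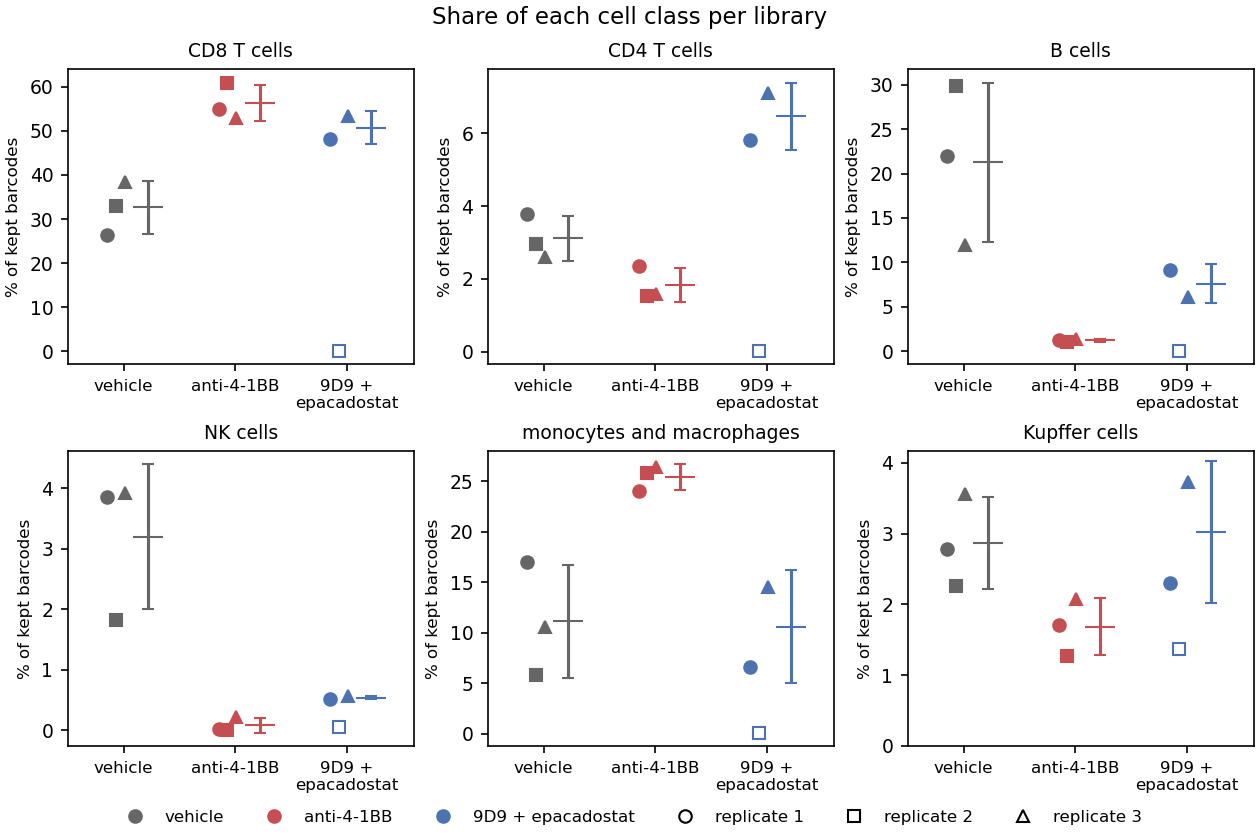
Percent of kept barcodes in each of 6 cell classes, 1 panel per class, with 1 marker per library (shape gives the replicate, color the group). The dash and bar beside the markers give mean and SD, without replicate 2 of 9D9 + epacadostat, which is drawn open. B-like cells were 1.00% to 1.37% in the anti-4-1BB libraries and 11.9% to 29.9% in the vehicle libraries.

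In all CD45+ cells anti-4-1BB raised cell cycle genes, and Jchain and several B cell genes fell. Ccna2, a cyclin of S and G2 phase, rose by 3.09 ± 0.28 (log2, SE, n = 3 against 3, edgeR), Prtn3, a protease of immature myeloid cells, by 3.17 ± 0.76, and the monocyte attractant Ccl8 by 3.58 ± 0.89. Jchain, which joins secreted immunoglobulin, fell by 9.95 ± 0.67, from 350 CPM in vehicle to 0.322 CPM. The B cell genes Pax5 (-4.93 ± 0.48), Vpreb3 (-4.81 ± 0.53) and Fcer2a (-4.72 ± 0.52) fell with the share of B-like cells. Elane, the elastase gene of neutrophil precursors, was at least 263-fold higher, with 1578 UMIs against 0 in vehicle (floor of 3 UMIs over the group). Of 12459 genes tested by edgeR, 2980 rose and 2710 fell.

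By camera p, division genes led the fixed lists whose p is given for this comparison. Of 33 proliferation genes 29 rose and 1 fell (32 and 1 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 2e-14; adjusted p = 0.452 with an estimated correlation). They included Mcm7 (1.62 ± 0.10) and Mcm5 (1.91 ± 0.15), which encode subunits of the replication helicase, Plk1 (3.02 ± 0.22), a mitotic kinase, and Tyms (2.26 ± 0.18). In the type I interferon list 17 of 29 rose and 1 fell (camera adjusted p = 0.00055; adjusted p = 0.534 with an estimated correlation), with Irf7 at 1.57 ± 0.18, Ifi27l2a at 1.40 ± 0.15, Rtp4 at 1.26 ± 0.15 and Xaf1 at 0.99 ± 0.13. Interferon-gamma genes rose in 10 of 30 and fell in 1 (adjusted p = 0.0236; 0.791 as the adjusted p with an estimated correlation), among them Psmb10 (0.92 ± 0.12) and Tapbp (0.84 ± 0.13) of antigen processing. Of 18 monocyte genes 11 rose and 0 fell (adjusted p = 0.00248; adjusted p = 0.438 with an estimated correlation), led by Ly6c2 (2.13 ± 0.19) and S100a10 (1.18 ± 0.11). Among 29 inflammatory cytokines and chemokines 3 rose and 4 fell, with Il18 (1.34 ± 0.18) and Osm (1.17 ± 0.19) up and Nfkbiz (-0.75 ± 0.11) and Cxcl13 (-2.48 ± 0.58) down. Tryptophan and aryl hydrocarbon receptor genes rose in 2 of 12 and fell in 5, with Ahr at -1.44 ± 0.22 and Kmo at -1.30 ± 0.24. Of 22 Kupffer identity genes 2 rose and 3 fell, and of 6 genes in the acute phase list Hp (0.73 ± 0.19) and Saa3 (1.44 ± 0.44) rose. Saa3 was among the leading genes of macrophage-like cluster 2 and Hp of monocyte-like finer cluster 10, so neither rise shows a hepatocyte response.

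RNA of other cells and of cell handling moved with the same groups. Hepatocyte transcripts, which CD45 enrichment should remove, fell in 10 of 23 and rose in 0 (camera adjusted p = 0.00409; adjusted p = 0.701 with an estimated correlation), such as Fga (-2.46 ± 0.63). Erythroid transcripts, which lysis of red cells should remove, rose in 7 of 8 (adjusted p = 0.00293; adjusted p = 0.532 with an estimated correlation). Hba-a1 reached 520 CPM against 1.72 in vehicle, and erythroid-like cells were 0.261% of barcodes under anti-4-1BB and 0 in vehicle. Dissociation stress genes fell in 7 of 20 and rose in 1, with Jun at -1.52 ± 0.19, Btg2 at -0.93 ± 0.12 and Hspa8 at 0.79 ± 0.14. Without anti-4-1BB replicate 2 the comparison called 3620 genes in place of 5690.

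9D9 + epacadostat moved fewer genes past the threshold in all CD45+ cells, where 198 rose and 64 fell of 12459. Tnfrsf4, the gene of the costimulatory receptor OX40, rose by 1.76 ± 0.33 (log2, SE, n = 3 against 3, edgeR), the transcriptional repressor gene Crem by 1.73 ± 0.29, Thbs1 by 2.07 ± 0.44 and the neutrophil collagenase Mmp8 by 2.37 ± 0.48. Fchsd2 (-1.55 ± 0.28), Bank1 (-1.55 ± 0.33), a B cell adaptor, B3gnt5 (-1.76 ± 0.38) and Sesn1 (-1.43 ± 0.28) fell. Cell cycle genes rose in 5 of 33 (16 adjusted over the list alone), with Tk1 at 1.17 ± 0.20 and Tyms at 0.96 ± 0.18 (camera adjusted p = 4.7e-05; adjusted p = 0.608 with an estimated correlation). Type I interferon genes fell in 2 of 29 and rose in 0 (11 and 1 adjusted over the list alone), with Ifit1 at -1.19 ± 0.24 and Stat2 at -0.89 ± 0.19 (adjusted p = 0.00121; adjusted p = 0.557 with an estimated correlation). Of 30 interferon-gamma genes Tgtp2 (-1.54 ± 0.32) and Ciita (-0.90 ± 0.19) fell. Monocyte genes rose in 4 of 18, such as Ly6c2 (0.96 ± 0.18) and S100a10 (0.57 ± 0.10), with a camera adjusted p = 0.00623 (adjusted p = 0.452 with an estimated correlation). In the acute phase list Orm1 (2.50 ± 0.42) and Lcn2 (2.94 ± 0.58) rose, and Lcn2 was among the leading genes of neutrophil-like cluster 12. As for RNA of other cells, erythroid transcripts were higher as a set, with a median of 6.25 and 0 of 8 past the threshold (camera adjusted p = 0.0204; adjusted p = 0.625 with an estimated correlation), and 0 of 23 hepatocyte transcripts passed.

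These counts rested on single libraries. The 262 genes became 0 without vehicle replicate 1 or 2, anti-4-1BB replicate 2 or 3 or 9D9 + epacadostat replicate 1, 7 without vehicle replicate 3 and 5 without 9D9 + epacadostat replicate 2, the shallow library. They became 1758 without anti-4-1BB replicate 1 and 1724 without 9D9 + epacadostat replicate 3. DESeq2 called 1912 genes, of which 57.2% were higher, against 75.6% in edgeR.

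Set directly against anti-4-1BB, 9D9 + epacadostat had 761 genes higher and 1012 lower in all CD45+ cells. The killer cell lectin receptor gene Klrg1 (-3.05 ± 0.18, SE, n = 3 against 3, edgeR), Plk1 (-2.07 ± 0.21) and Upp1 (-2.03 ± 0.40) were lower, and Jchain (8.87 ± 0.65), the dendritic cell lectin gene Cd209a (4.28 ± 0.65) and Vpreb3 (3.77 ± 0.53) were higher. Of 33 proliferation genes 27 were lower (camera adjusted p = 1.34e-19; adjusted p = 0.387 with an estimated correlation). So were 20 of 29 type I interferon genes (adjusted p = 4.45e-13; adjusted p = 0.352 with an estimated correlation) and 15 of 30 interferon-gamma genes (adjusted p = 5.48e-06; adjusted p = 0.525 with an estimated correlation). Without 9D9 + epacadostat replicate 2 these 3 lists gave 26, 16 and 8 lower genes. Hepatocyte transcripts were higher in 7 of 23 and stress genes in 5 of 20, and erythroid transcripts were lower as a set, with a median of -1.86 and 0 of 8 past the threshold (adjusted p = 0.0132; adjusted p = 0.608 with an estimated correlation). The count of 1773 fell to 424 without anti-4-1BB replicate 2, 535 without anti-4-1BB replicate 3 and 1122 without 9D9 + epacadostat replicate 3.

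In CD8 T-like cells anti-4-1BB raised genes of division and glycolysis and lowered naive and central memory genes. Klrg1, a receptor of terminally differentiated effector cells (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882, minus strand), rose by 3.92 ± 0.28 (log2, SE, n = 3 against 3, edgeR adjusted p = 0.00013), from 7.56 to 113 CPM. Il7r, the receptor subunit for the survival cytokine IL-7 (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176, minus strand), fell by 2.72 ± 0.19, from 174 to 26.4 CPM. Gzma, encoding granzyme A (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981, minus strand), fell by 2.79 ± 0.25, from 4787 to 692 CPM, while Gzmb, encoding granzyme B, rose by 0.79 ± 0.17, from 500 to 867 CPM. Serpine2 (4.34 ± 0.44), Gcg (4.34 ± 0.71) and Ccna2 (2.58 ± 0.36) rose, and Hspa1a (-3.54 ± 0.56), a heat shock gene, and Fam101b (-3.004 ± 0.27) fell. Of 10707 genes 2757 rose and 2764 fell.

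Cytotoxic effector genes went both ways in these cells, with 7 of 21 up and 4 down (camera adjusted p = 0.711). Cst7 rose by 0.82 ± 0.18. Activation and checkpoint receptor genes also split, 6 of 20 up and 4 down. The agonist's own target Tnfrsf9 rose by 1.73 ± 0.17, to 209 from 62.8 CPM, and the activation factor Batf by 0.89 ± 0.18. The orphan nuclear receptor genes Nr4a2 (-1.85 ± 0.21) and Nr4a3 (-1.57 ± 0.27), induced by receptor signaling, fell. Naive and central memory genes fell in 13 of 15 and rose in 0 (camera adjusted p = 2.37e-06; adjusted p = 0.452 with an estimated correlation), including the transcription factor genes Foxp1 (-1.55 ± 0.13), Satb1 (-2.12 ± 0.23) and Bach2 (-2.57 ± 0.30). Of 13 residency and homing genes 7 fell and 2 rose (adjusted p = 0.0547). The integrin gene Itga1 (-3.37 ± 0.43), Ahr (-2.08 ± 0.21) and Cd69 (-1.37 ± 0.17), which marks retained cells, fell, and the chemokine receptor gene Ccr2 rose by 2.74 ± 0.24. Dissociation stress genes fell in these sums too, and handling was not told apart from signaling or retention in Nr4a2, Nr4a3 and Cd69.

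Proliferation genes rose in 26 of 33 in CD8 T-like cells and fell in 1 (28 and 1 adjusted over the list alone), with Plk1 at 2.56 ± 0.23, Tk1 at 2.31 ± 0.26 and Mcm7 at 1.66 ± 0.20 (camera adjusted p = 1.66e-08; adjusted p = 0.524 with an estimated correlation). Glycolysis genes rose in 13 of 17 and fell in 1, with Gapdh at 1.84 ± 0.18, Ldha at 1.89 ± 0.20 and Tpi1 at 2.09 ± 0.23 (adjusted p = 0.000276; adjusted p = 0.488 with an estimated correlation). Interferon genes showed no common direction. In the interferon-gamma list 9 of 29 rose, such as Psmb9 (0.66 ± 0.10) and Gbp3 (0.92 ± 0.15), and 9 fell. In the type I list 3 of 27 rose, Zbp1 (0.80 ± 0.15) among them, and 8 fell, such as Stat2 (-1.04 ± 0.20) and Ifit1 (-1.69 ± 0.36). Tryptophan and aryl hydrocarbon receptor genes fell in 6 of 11 and rose in 2, with Tiparp at -0.95 ± 0.17 and the amino acid transporter gene Slc7a5 at 1.4996 ± 0.30. Of 12 regulatory T genes 4 rose, Capg (1.58 ± 0.29) among them, and 2 fell, Itgae (-1.92 ± 0.28) among them.

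Different clusters filled the CD8 T-like class in each group. Cluster 6 (Gzma, Tox, Nr4a2) held 57.6% to 71.7% of it in vehicle libraries, and clusters 3 (cycling), 5 and 7 held 31.4% to 40.6%, 22.4% to 40.4% and 25.9% to 28.7% under anti-4-1BB. Under anti-4-1BB cluster 6 held 0.0365% to 5.40%. Cluster 14, led by Dapl1, Lef1, Tcf7 and Il7r, held 11.4% to 20.7% in vehicle and 1.51% to 1.92% under anti-4-1BB. How far this makeup carries the falls of Gzma, Il7r and naive genes was not tested. Stress genes fell in 7 of 20, with Btg2 at -1.55 ± 0.12 and Jun at -1.90 ± 0.30, hepatocyte transcripts fell in 16 of 17, with Ttr at -2.26 ± 0.34, and erythroid transcripts rose in 4 of 5. Barcodes with a Cd4 UMI were 14.9% to 17.3% of the class under anti-4-1BB (median 4407 to 4915 UMIs) and 2.71% to 5.20% in vehicle (2494 to 3013 UMIs), against 0% to 3.23% of B-like barcodes. No left-out library moved the count of 5521 genes by more than 1.5 times.

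**Figure D2:**
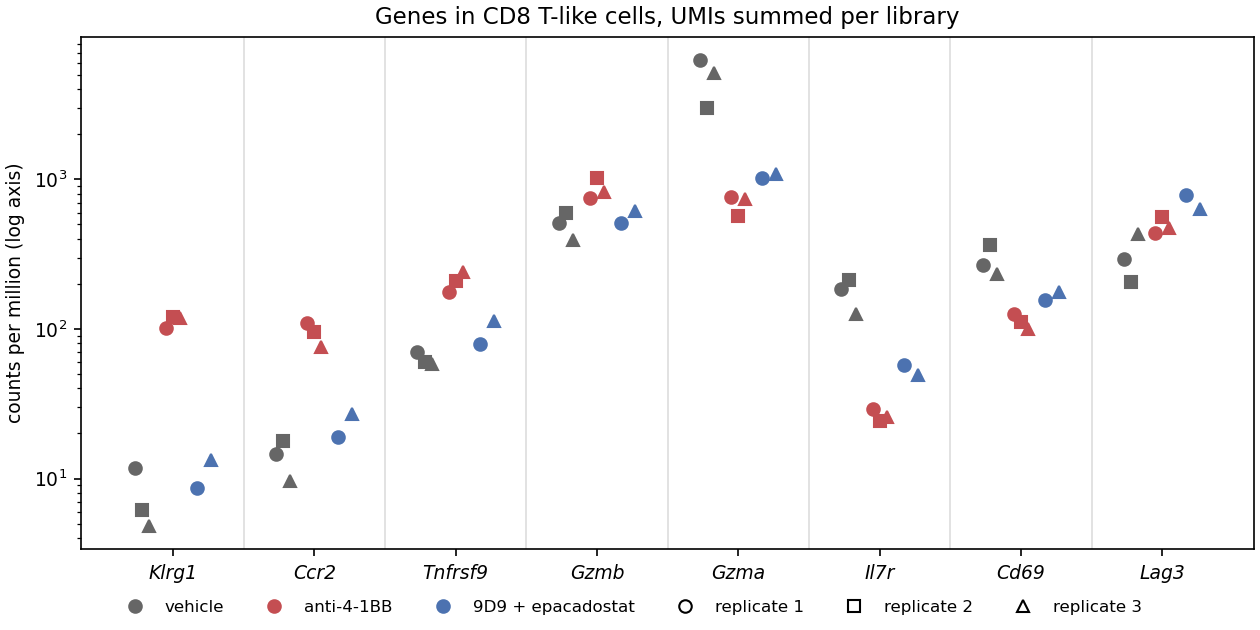
CPM (log axis) of 8 genes in CD8 T-like cells, with UMIs summed per library and 1 marker per library (shape gives the replicate, color the group). Replicate 2 of 9D9 + epacadostat is not drawn, because it had 11 such barcodes. Klrg1, Ccr2 and Tnfrsf9 lie above vehicle in the 3 anti-4-1BB libraries, and Gzma and Il7r lie below vehicle in all 5 treated libraries.

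9D9 + epacadostat also lowered Gzma and Il7r in CD8 T-like cells. Gzma fell by 2.18 ± 0.28 (log2, SE, n = 2 against 3, edgeR adjusted p = 0.037), to 1058 CPM from 4787, and Il7r by 1.72 ± 0.22 (adjusted p = 0.0318). The survival gene Bcl2 (-1.58 ± 0.20, adjusted p = 0.0318) and Klf3 (-1.62 ± 0.17, adjusted p = 0.0117) fell. S100a4, the only other gene called, rose by 1.29 (adjusted p = 0.0117) and was named after its value was seen, since the fixed rule left it out as a monocyte marker. Naive and central memory genes fell in 1 of 15 (13 adjusted over the list alone), with Lef1 at -1.64 ± 0.25 (adjusted p = 0.0639), a camera adjusted p = 4.67e-09 and an adjusted p = 0.376 with an estimated correlation. Activation genes passed in 0 of 20 (7 higher adjusted over the list alone; camera adjusted p = 0.0105; adjusted p = 0.488 with an estimated correlation). Lag3 stood at 1.19 ± 0.26 (adjusted p = 0.0833) and Icos at 1.23 ± 0.21 (adjusted p = 0.0639). Glycolysis genes passed in 0 of 17 (10 higher and 1 lower adjusted over the list alone), with Gapdh at 1.09 ± 0.19 (adjusted p = 0.0639), a camera adjusted p = 0.00936 and an adjusted p = 0.579 with an estimated correlation. Hepatocyte transcripts were lower here too as a set (camera adjusted p = 5.27e-09; adjusted p = 0.388 with an estimated correlation), with 0 of 17 past the threshold and 11 lower adjusted over the list alone.

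The 5 genes compare with 2241 at an unadjusted p under 0.05, 334 in DESeq2 (66.2% higher, against 1 of 5 in edgeR) and 371 without a filter on low counts. Without 1 library the count was 0 (vehicle replicate 1), 31 (vehicle replicate 3), 806 (anti-4-1BB replicate 1), 2 (anti-4-1BB replicate 3), 1 (9D9 + epacadostat replicate 1) and 2 (9D9 + epacadostat replicate 3). Both usable libraries differed in composition, with cluster 5 holding 55.4% of the class in replicate 1 and cluster 9 holding 63.4% in replicate 3. Cluster 6 held 1.55% and 13.8% in replicates 1 and 3, against 57.6% to 71.7% in vehicle. Cluster 14, led by Dapl1, Lef1, Tcf7 and Il7r, held 4.95% and 3.77%, against 11.4% to 20.7%. How far this makeup carries the falls of Gzma, Il7r and naive genes was not tested.

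Against anti-4-1BB, CD8 T-like cells under 9D9 + epacadostat had higher residency genes and lower division and glycolysis genes. Klrg1 was lower (-3.30 ± 0.31, SE, n = 2 against 3, edgeR), as were Gcg (-5.98 ± 0.99), Serpine2 (-3.37 ± 0.46) and Tnfrsf9 (-1.10 ± 0.19, adjusted p = 0.00894), and Hspa1a (5.29 ± 0.57), Cebpb (4.15 ± 0.67) and Ier5l (3.29 ± 0.28) were higher. Of 13 residency genes 6 were higher and 1 lower (camera adjusted p = 0.00936; adjusted p = 0.352 with an estimated correlation). Proliferation genes were lower in 25 of 33 (adjusted p = 1.6e-10; adjusted p = 0.504 with an estimated correlation) and glycolysis genes in 7 of 17 (adjusted p = 0.00145; adjusted p = 0.512 with an estimated correlation). Stress genes were higher in 7 of 20 (adjusted p = 0.00732; adjusted p = 0.488 with an estimated correlation). Clusters 5 and 9 held most of the class in the 9D9 + epacadostat libraries, and clusters 3, 5 and 7 under anti-4-1BB. The count of 1878 (788 higher, 1090 lower) became 3184 without anti-4-1BB replicate 1, 748 and 482 without anti-4-1BB replicates 2 and 3, 835 and 45 without 9D9 + epacadostat replicates 1 and 3, and 571 without the cycling cluster.

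Both treatments moved CD8 T-like genes in like directions, as far as shared controls let this be read. Over 10707 genes the fold changes of both treatments had a Pearson r of 0.693 and a Spearman rho of 0.712. Simulated unchanged groups that shared their vehicle libraries, which were simulated too, gave 0.494 and 0.463. Genes are not independent replicates. The covariance was 0.387 against 0.0527 simulated, a difference of 0.334, and 78.1% of genes had the same sign against 66.3%. Klf3, Bcl2, Il7r and Gzma fell and S100a4 rose under both treatments, where independent lists would share 1.03 falling and 0.257 rising genes. In monocytes and macrophages r was 0.572 and rho 0.610 (0.464 and 0.444 simulated), the covariance 0.178 against 0.0612, and 0 calls were shared. With 3 vehicle libraries the controls could not be split, so part of the excess may come from them. Leaving out a vehicle library gave 0 to 31 shared calls in CD8 T-like cells.

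CD4 T-like cells are the regulatory T-like cluster, with Foxp3, Cd4 and Tnfrsf4 among its leading genes. Barcodes with a Cd8 UMI were 24.4% to 46.5% of it, against 2.72% to 22.6% of B-like barcodes. Barcodes with a Cd4 UMI were 49.6%, 59.4% and 30.6% of it in vehicle libraries, 73.3%, 76.8% and 61.1% under anti-4-1BB and 53.8% and 62.8% under 9D9 + epacadostat, so its makeup or depth differed with the groups. Anti-4-1BB lowered memory and stress genes there and raised glycolysis genes. Nr4a3 fell by 4.00 ± 0.44 (log2, SE, n = 3 against 3, edgeR), Nr4a2 by 2.47 ± 0.25, the immediate early gene Fosb by 2.32 ± 0.56 and Tbc1d4 by 2.14 ± 0.42. Klrg1 (2.09 ± 0.44), Fam110a (1.92 ± 0.40), Asb2 (1.90 ± 0.45) and Pglyrp1 (1.89 ± 0.19) rose. Naive and central memory genes fell in 5 of 11, with Il7r at -1.50 ± 0.20 and Foxp1 at -1.62 ± 0.29 (camera adjusted p = 0.00661; adjusted p = 0.524 with an estimated correlation). Residency genes rose in 3 of 9, with Ccr2 at 2.07 ± 0.37, and fell in 3, with Ahr at -2.57 ± 0.46. Activation genes fell in 4 of 19 and rose in 1, and regulatory T genes rose in 3 of 13, such as Capg (1.03 ± 0.22), and fell in 1, Ikzf2 (-0.78 ± 0.17).

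Some interferon genes rose in these regulatory T-like cells, although neither list passed as a set. Type I genes rose in 6 of 16 and fell in 0 (camera adjusted p = 0.0742), with Ifi27l2a at 1.54 ± 0.17, Irf7 at 1.19 ± 0.30 and Isg20 at 1.35 ± 0.32, and interferon-gamma genes rose in 7 of 22 and fell in 1 (adjusted p = 0.0726), with Tapbp at 0.90 ± 0.20. Lyz2, a myeloid gene, rose from 172 ± 9.67 to 461 ± 145 CPM (SD, n = 3) in these sums. If all of it came from monocytes and macrophages, they would bring 1.54% to 2.48% of the UMIs of type I genes and 1.61% to 3.18% of those of interferon-gamma genes in the anti-4-1BB libraries, a bound computed after the data were seen. Glycolysis genes rose in 4 of 15, with Gapdh at 1.23 ± 0.20 (adjusted p = 0.00113; adjusted p = 0.512 with an estimated correlation). Stress genes fell in 8 of 19 and rose in 1, with Btg2 at -1.20 ± 0.17 and Fos at -1.36 ± 0.21 (adjusted p = 0.00208; adjusted p = 0.352 with an estimated correlation). The edgeR count of 844 (395 up, 449 down) rests on 36 to 127 barcodes per library and became 480, 275 and 387 without vehicle replicates 1, 2 and 3, and 1347, 204 and 374 without anti-4-1BB replicates 1, 2 and 3. With T cells split by Cd8 and Cd4 UMIs, Asb2 (-0.24), Nr4a2 (0.33), Cxcr3 (-0.13) and Capg (-0.64) turned direction and none of these passed.

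9D9 + epacadostat raised checkpoint receptor genes in the sums of CD4 T-like cells, which include barcodes with Cd8 UMIs. Lag3, an inhibitory receptor of activated T cells, rose by 2.44 ± 0.26 (log2, SE, n = 2 against 3, edgeR adjusted p = 0.00105), to 1020 from 190 CPM, and Havcr2, encoding TIM-3, by 1.41 ± 0.30. Gpm6b (2.003 ± 0.37), Ccrl2 (1.74 ± 0.29), Fosl2 (1.62 ± 0.25) and Cst7 (1.30 ± 0.26) rose. Bcl2 (-1.52 ± 0.27), Ifi47 (-1.44 ± 0.26), Clec2d (-1.30 ± 0.28), Cd69 (-1.29 ± 0.24) and Il7r (-1.08 ± 0.21) fell. Activation genes rose in 2 of 19 (5 adjusted over the list alone; camera adjusted p = 0.000186; adjusted p = 0.376 with an estimated correlation), and type I interferon genes fell in 1 of 16 (adjusted p = 0.00729; adjusted p = 0.352 with an estimated correlation). Barcodes with a Cd8 UMI were 37.2% and 46.5% of the class under 9D9 + epacadostat, and 24.4%, 33.0% and 41.7% in vehicle. Nkg7, a gene of T and NK cells, stood at 2446 ± 688 CPM (SD, n = 3) in these sums in vehicle, against 4574 ± 762 CPM in CD8 T-like sums. Lag3 was among the 10 leading genes of CD8 T-like clusters 5 and 9, so how far CD8 T-like cells carry these rises stays open. Of 5373 genes 22 rose and 8 fell. The count of 30 became 4 and 1 without vehicle replicates 1 and 2, 166 and 49 without anti-4-1BB replicates 1 and 2, 49 without 9D9 + epacadostat replicate 3, and 0 with T cells split by Cd8 and Cd4 UMIs.

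Between the treatments, CD4 T-like cells under 9D9 + epacadostat were higher in activation genes and lower in interferon genes. Nr4a3 (3.97 ± 0.45, SE, n = 2 against 3, edgeR), Fosl2 (3.63 ± 0.33) and Nrgn (3.14 ± 0.64) were higher, and Klrg1 (-2.84 ± 0.51), Rtp4 (-1.91 ± 0.40) and Irf7 (-1.67 ± 0.33) were lower. Activation genes were higher in 6 of 19 (camera adjusted p = 1.19e-05; adjusted p = 0.352 with an estimated correlation). Type I interferon genes were lower in 5 of 16 (8 adjusted over the list alone; adjusted p = 6.17e-07; adjusted p = 0.144 with an estimated correlation). Stress genes were higher in 3 of 19 (adjusted p = 0.00344; adjusted p = 0.352 with an estimated correlation). Activation and cell handling were not told apart in Nr4a3 and the other activation genes. The 113 genes (67 higher, 46 lower) became 345 and 61 without anti-4-1BB replicates 1 and 3 and 41 without 9D9 + epacadostat replicate 3.

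In monocytes and macrophages anti-4-1BB raised interferon-stimulated genes and lowered Cx3cr1 and Fn1. Ifi44 rose by 2.74 ± 0.32 (log2, SE, n = 3 against 3, edgeR adjusted p = 0.00971), Irf7, the regulator of interferon-alpha transcription, by 1.56 ± 0.26, Rtp4 by 1.37 ± 0.19 and Ifi27l2a by 1.02 ± 0.14. The fractalkine receptor gene Cx3cr1 (-2.25 ± 0.38), fibronectin gene Fn1 (-2.005 ± 0.28), Cd177 (-1.86 ± 0.34) and Gpr183 (-1.61 ± 0.28) fell, and Slc28a2 (1.43 ± 0.21) and Lat (1.56 ± 0.35), an adaptor of T cells, rose. Type I interferon genes rose in 6 of 29 (12 adjusted over the list alone; camera adjusted p = 4.66e-07; adjusted p = 0.512 with an estimated correlation). None of 30 interferon-gamma genes passed in edgeR, and their median was 0.48 (adjusted p = 0.000553; adjusted p = 0.701 with an estimated correlation). Proliferation genes rose in 3 of 25 (11 adjusted over the list alone), with Ube2c at 3.52 ± 0.62 (adjusted p = 8.69e-06; adjusted p = 0.376 with an estimated correlation). Nkg7, a gene of T and NK cells, stood at 154 ± 31.1 CPM (SD, n = 3) against 77.7 ± 46.8 CPM in vehicle. If all of it came from CD8 T-like cells, a bound computed after the data were seen, they would bring 9.17 of the 9.57 CPM of Ube2c, and 20.9% to 29.2% of the UMIs of proliferation genes in the anti-4-1BB libraries (34.7% to 58.1% if all from their cycling cluster), so T cells may carry the called division genes here. In vehicle libraries the bounds on proliferation genes were 4.63% to 12.6% (30.9% to 60.9% if all from the cycling cluster). Genes of MHC class II presentation rose in 2 of 14, H2-DMb1 (0.71 ± 0.12) and H2-DMa (0.64 ± 0.14), which load peptide (adjusted p = 0.00561; adjusted p = 0.534 with an estimated correlation). Phagocytosis genes rose in 3 of 16, with the Fc receptor genes Fcgr1 at 1.07 ± 0.17 and Fcgr3 at 0.97 ± 0.18 (adjusted p = 0.0328; adjusted p = 0.541 with an estimated correlation).

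Other myeloid lists moved little in this class. Inflammatory genes gave 1 rise, Il18 (1.14 ± 0.22), and 1 fall, Nfkbiz (-0.92 ± 0.18), of 29, the monocyte list 1 rise, Ms4a4c (0.75 ± 0.18), and 1 fall of 18, and 0 of 20 lipid-associated macrophage genes passed in edgeR. Stress genes fell in 2 of 20, Jun (-0.94 ± 0.16) and Fosb (-1.26 ± 0.25), hepatocyte transcripts in 2 of 8, Trf (-1.05 ± 0.23) and Apoa2 (-1.66 ± 0.38), and erythroid transcripts rose in 3 of 5, with Hbb-bt at 3.58 ± 0.50. Macrophage-like cluster 2 outnumbered monocyte-like cluster 8 in all usable libraries but vehicle replicate 2 (81 against 127 barcodes). The makeup within monocytes differed with the groups, since finer cluster 10 held 24, 20 and 7 barcodes in vehicle libraries and 482, 394 and 182 under anti-4-1BB, and finer cluster 16 held 92, 119 and 125 and then 12, 4 and 7. The 317 genes (164 up, 153 down, of 9754) became 53, 201 and 23 without vehicle replicates 1, 2 and 3, 2051 without anti-4-1BB replicate 1, 4 without anti-4-1BB replicate 2 or 3, and 176 and 185 without 9D9 + epacadostat replicates 1 and 3. DESeq2 called 514 genes, the fit of only 2 groups 158 and the replicate block 33.

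9D9 + epacadostat changed 0 genes in monocytes and macrophages by edgeR, with 1047 at an unadjusted p under 0.05 and 5 called by DESeq2. The chemokine gene Ccl7 stood at 2.03 ± 0.48 (log2, SE, n = 2 against 3, edgeR adjusted p = 0.381), Thbs1 at 1.94 ± 0.46 (adjusted p = 0.382) and H2-DMb1 at 0.47 ± 0.13. MHC class II genes had a median of 0.39 with 0 of 14 past the threshold (camera adjusted p = 0.00711; adjusted p = 0.541 with an estimated correlation), and Kupffer identity genes a median of 0.42 (adjusted p = 0.00362; adjusted p = 0.493 with an estimated correlation). Without 9D9 + epacadostat replicate 3 the count was 3, and without a filter on low counts 46.

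Set against anti-4-1BB, monocytes and macrophages of the 9D9 + epacadostat group gave 5 called genes. The interferon lists were lower by camera with the preset correlation, with 1 type I gene past the threshold. Ifi44 was lower (-2.88 ± 0.41, SE, n = 2 against 3, edgeR adjusted p = 0.0405) and Klf4 higher (1.60 ± 0.20, adjusted p = 0.0222). The other 3 genes called were higher and were named after their values were seen: Gm1673 (2.75), the B cell gene Cd79a (2.94) and the hepatocyte list gene Trf (2.15). Type I interferon genes were lower in 1 of 29 (16 adjusted over the list alone) with a median of -0.89 (camera adjusted p = 3.86e-13; adjusted p = 0.452 with an estimated correlation), and interferon-gamma genes had a median of -0.48 (adjusted p = 4.21e-05; adjusted p = 0.625 with an estimated correlation). The 5 genes became 8 and 19 without vehicle replicates 1 and 3, 20 without anti-4-1BB replicate 1, 0 without anti-4-1BB replicate 2 or 3, and 3 and 2 without 9D9 + epacadostat replicates 1 and 3. DESeq2 called 69.

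In Kupffer-like cells, the resident macrophages of the liver, anti-4-1BB raised division, glycolysis and interferon genes and lowered stress genes. Stmn1 rose by 2.39 ± 0.28 (log2, SE, n = 3 against 3, edgeR), Tk1 by 2.29 ± 0.35, Birc5 by 2.87 ± 0.37 and Il18, an inflammasome cytokine, by 1.94 ± 0.23. Klf4 (-2.30 ± 0.27), the complement receptor gene C3ar1 (-1.82 ± 0.29), the mannose receptor gene Mrc1 (-1.14 ± 0.20) and Stab1 (-1.34 ± 0.32), a scavenger receptor gene, fell. Proliferation genes rose in 12 of 20 (14 adjusted over the list alone; camera adjusted p = 1.4e-09; adjusted p = 0.144 with an estimated correlation). RNA of T cells moved too, since Nkg7, a gene of T and NK cells, went from 85.3 ± 25.8 CPM (SD, n = 3) in vehicle to 228 ± 52.9 CPM in Kupffer-like sums. If all of it came from CD8 T-like cells, a bound computed after the data were seen, they would bring 10.5% to 23.6% of the UMIs of proliferation genes in the anti-4-1BB libraries, and 20.8% to 40.6% if all came from their cycling cluster. Glycolysis genes rose in 8 of 14 and fell in 1, with Gapdh at 1.32 ± 0.17 and Aldoa at 1.14 ± 0.18 (adjusted p = 2.69e-05; adjusted p = 0.152 with an estimated correlation). Interferon-gamma genes rose in 8 of 25, with Gbp7 at 1.02 ± 0.20 and Psmb8 at 0.81 ± 0.17 (adjusted p = 1.9e-05; adjusted p = 0.488 with an estimated correlation), and type I genes in 7 of 26, with Zbp1 at 1.23 ± 0.20, Irf7 at 1.09 ± 0.20 and Isg15 at 1.02 ± 0.20 (adjusted p = 0.0039; adjusted p = 0.452 with an estimated correlation).

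The remaining lists were mixed in Kupffer-like cells. Kupffer identity genes gave 1 rise, the heme oxygenase gene Hmox1 (1.00 ± 0.18), and 1 fall, the complement gene C6 (-0.87 ± 0.22), of 22. Lipid-associated macrophage genes rose in 2 of 18, Ctsd (1.00 ± 0.18) among them, and Apoe fell (-1.21 ± 0.29), but without 9D9 + epacadostat replicate 2 in the fit 4 of 19 rose and 0 fell. Phagocytosis genes rose in 2 and fell in 2 of 17, inflammatory genes rose in 3 and fell in 2 of 22, and monocyte genes rose in 2 of 16, with Plac8 at 1.46 ± 0.21 (camera adjusted p = 0.0112; adjusted p = 0.493 with an estimated correlation). Stress genes fell in 6 of 19, with Hspa1a at -3.54 ± 0.39 and Jun at -1.97 ± 0.25 (adjusted p = 0.000724; adjusted p = 0.488 with an estimated correlation). Pdcd1 passed (2.62 ± 0.79, adjusted p = 0.0378) on 0 to 18 UMIs in each of the 6 libraries, and the same bound on RNA of CD8 T-like cells would bring 19.7 of its 20.2 CPM under anti-4-1BB, so the call does not show expression by Kupffer-like cells. The 560 genes (285 up, 275 down, of 5595) became 177, 377 and 194 without vehicle replicates 1, 2 and 3, and 175 and 178 without anti-4-1BB replicates 2 and 3. DESeq2 called 193 genes. The finer Kupffer-like cluster held 40, 26 and 37 barcodes in the anti-4-1BB libraries, where this class held 76, 57 and 47. In vehicle libraries it held 55, 68 and 62, where the class held 93, 81 and 99. Part of the class was thus not Kupffer-like at that resolution.

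9D9 + epacadostat raised lipid-associated macrophage and glycolysis genes in Kupffer-like cells. Hilpda, a lipid droplet gene, rose by 2.68 ± 0.39 (log2, SE, n = 3 against 3, edgeR), Lgals1 by 2.06 ± 0.30, the fatty acid binding gene Fabp5 by 2.02 ± 0.41, and Cd9 by 1.34 ± 0.31. Clec2d (-1.43 ± 0.27), Mrc1 (-1.01 ± 0.21), the iron exporter gene Slc40a1 (-0.85 ± 0.17) and C6 (-0.92 ± 0.23) fell. Lipid-associated macrophage genes rose in 3 of 18 (camera adjusted p = 0.00067; adjusted p = 0.488 with an estimated correlation), glycolysis genes in 4 of 14 (8 adjusted over the list alone; adjusted p = 5.16e-06; adjusted p = 0.144 with an estimated correlation) and proliferation genes in 2 of 20, Stmn1 (1.496 ± 0.31) and Tk1 (1.78 ± 0.39) (adjusted p = 0.00175; adjusted p = 0.352 with an estimated correlation). In replicate 1, where Nkg7 reached 516 CPM, the bound on RNA of CD8 T-like cells was 29.4% of the UMIs of proliferation genes and over 100% if from the cycling cluster, so T cells may carry the division genes there. In replicate 3 it was 8.25% and 34.6%, and in replicate 2 it was not computed. Type I interferon genes fell in 1 of 26, Ifi204 (-0.91 ± 0.22), with a median of -0.68 (adjusted p = 1.74e-05; adjusted p = 0.352 with an estimated correlation), and in 0 of 27 without the shallow replicate 2 (camera adjusted p = 5.99e-05). Of 5595 genes 45 rose and 23 fell. The 68 genes became 18, 30 and 28 without vehicle replicates 1, 2 and 3, 118 without anti-4-1BB replicate 1, and 30 and 182 without 9D9 + epacadostat replicates 1 and 3. They became 62 without the shallow replicate 2. The finer Kupffer-like cluster held 18, 107 and 70 barcodes in 9D9 + epacadostat replicates 1, 2 and 3, where this class held 31, 107 and 141. Fabp5 was among the leading genes of finer cluster 11, which was closest to monocyte-derived macrophages. How far such cells carry the rises named here was not tested.

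Between the treatments, Kupffer-like cells of the 9D9 + epacadostat group were lower in interferon genes and higher in stress genes. Ifit3 (-1.66 ± 0.34, SE, n = 3 against 3, edgeR), Igtp (-1.59 ± 0.29) and Xaf1 (-1.54 ± 0.35) were lower, and Hspa1a (2.75 ± 0.42), Cd83 (2.53 ± 0.31) and Klf4 (1.97 ± 0.29) were higher. Type I genes were lower in 11 of 26 (19 adjusted over the list alone; camera adjusted p = 3.49e-17; adjusted p = 0.144 with an estimated correlation) and interferon-gamma genes in 6 of 25 (adjusted p = 1.37e-11; adjusted p = 0.352 with an estimated correlation). Stress genes were higher in 6 of 19 (adjusted p = 3.18e-08; adjusted p = 0.352 with an estimated correlation), inflammatory genes higher in 4 of 22 and lower in 1 (adjusted p = 0.00293; adjusted p = 0.512 with an estimated correlation). Without 9D9 + epacadostat replicate 2 the type I and interferon-gamma lists gave 9 and 4 lower genes, and the stress and inflammatory lists 4 and 2 higher ones (camera adjusted p = 0.0411 for the inflammatory list). The 76 genes (37 higher, 39 lower; 60.7% higher in DESeq2, 48.7% in edgeR) became 47 and 31 without anti-4-1BB replicates 2 and 3, and 66 without 9D9 + epacadostat replicate 2.

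**Figure D3:**
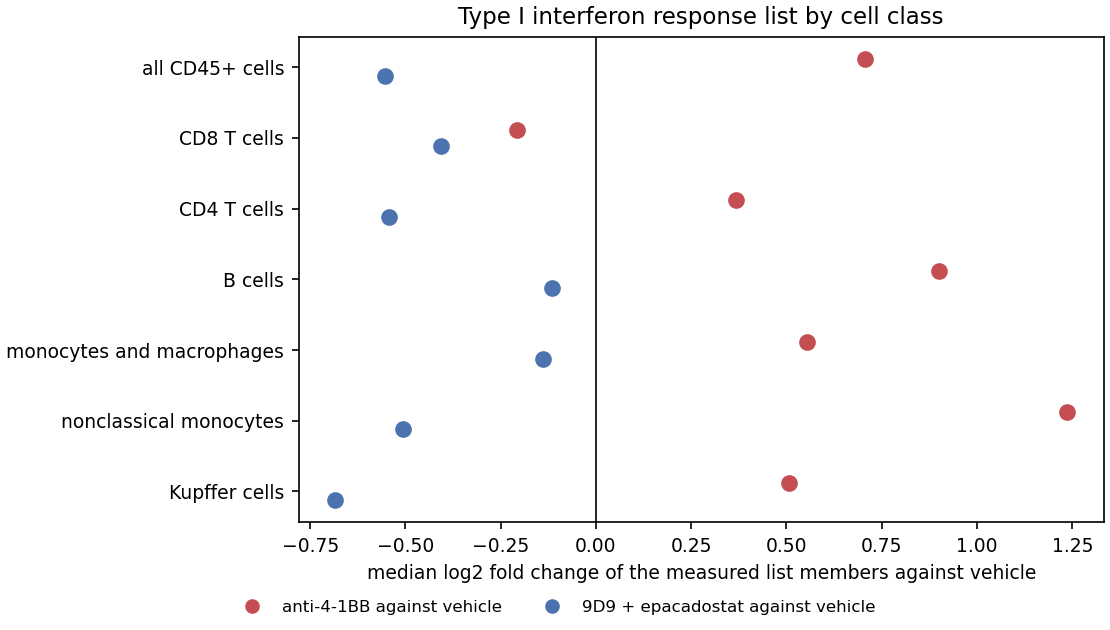
Median log2 fold change against vehicle of the measured members of the type I interferon list, by cell class, for anti-4-1BB (n = 3 against 3) and 9D9 + epacadostat (n = 3 against 3 in all CD45+ cells and Kupffer-like cells, n = 2 against 3 elsewhere). The median under 9D9 + epacadostat lies below 0 in all CD45+ cells (-0.55) and Kupffer-like cells (-0.68). Under anti-4-1BB it was 0.71 and 0.51, and in CD8 T-like cells -0.21.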

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

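The differences below were planned tests, and the values without replicate 2 of 9D9 + epacadostat were added after the data were seen. In all CD45+ cells the type I interferon list had a median log2 fold change of -1.04 in 9D9 + epacadostat minus anti-4-1BB, because it stood at 0.71 under anti-4-1BB and -0.55 under 9D9 + epacadostat against the same vehicle libraries (camera adjusted p = 4.45e-13; adjusted p = 0.352 with an estimated correlation). Without replicate 2 of 9D9 + epacadostat this median was -1.05, with 16 of 29 genes lower. These sums mix classes whose shares differed. Monocytes and macrophages were 25.4% under anti-4-1BB and 10.6% (n = 2) under 9D9 + epacadostat, and B-like cells 1.22% and 7.61%. Makeup and change within cells were not told apart in these sums. Irf7 shows the rise under anti-4-1BB only, with 93.3, 76.1 and 59.8 CPM in vehicle libraries, 185, 257 and 238 CPM under anti-4-1BB, and 69.2, 77.6 and 66.5 CPM under 9D9 + epacadostat, within the range of vehicle.

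Kupffer-like cells differed in the same list by -1.02, with medians of 0.51 and -0.68 under the 2 treatments (camera adjusted p = 3.49e-17; adjusted p = 0.144 with an estimated correlation). Without replicate 2 of 9D9 + epacadostat the difference was -1.04. Members lower in 9D9 + epacadostat than in anti-4-1BB included Ifit3 (-1.66 ± 0.34, SE, n = 3 against 3, edgeR) and Xaf1 (-1.54 ± 0.35). The widest difference of the 3 was in nonclassical monocytes, at -2.14 with medians of 1.24 and -0.51 (camera adjusted p = 1.84e-15; adjusted p = 0.352 with an estimated correlation), where Ifit3 was lower by -3.26 ± 0.53 and Ifi47 by -3.57 ± 0.64 (n = 2 against 3). In each of these 3 classes the camera test of the list against vehicle went up under anti-4-1BB and down under 9D9 + epacadostat. Under 9D9 + epacadostat it rested on the set, with 2 of 29, 1 of 26 and 0 of 21 genes lower past the threshold, and 0 in each without replicate 2 (with replicate 2 where it entered, camera adjusted p = 0.00121, 1.74e-05 and 0.00367; adjusted p = 0.557, 0.352 and 0.525 with an estimated correlation).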

How the results depend on the processing

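Thinned counts, the cycling cluster left out, and minor classes and lists without 9D9 + epacadostat replicate 2 were chosen after the data were seen. Over all alternatives 218 counts or shares stayed on their side of the threshold (counts within 1.5 times), 77 were weaker and 44 stronger. Of single genes 6623 values kept direction and call, 732 were weaker, 209 stronger and 4 reversed. The cause of each change below was not tested, except that a left-out library leaves fewer samples. 9D9 + epacadostat replicate 2 had 642 UMIs per kept barcode, and what limits this library was left open.

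Results are given in the order anti-4-1BB (a) or 9D9 + epacadostat (b) against vehicle, then 9D9 + epacadostat against anti-4-1BB (c). DESeq2 called 1912 (b) in all CD45+ cells, 334 (b) in CD8 T-like cells, 458 (a) and 74 (c) in CD4 T-like cells, 514 (a), 5 (b) and 69 (c) in monocytes and macrophages and 193 (a) in Kupffer-like cells. Its percent of higher genes moved by over 10 points in CD4 T-like cells (b, 63.0% against 73.3%) and monocytes (c, 69.6% against 80.0%), all CD45+ cells (b, 57.2% against 75.6%), CD8 T-like cells (b, 66.2% against 1 of 5) and Kupffer-like cells (c, 60.7% against 48.7%). Of its CD8 T-like calls it shared 5036 (a) and 5 (b) with edgeR. No filter on low counts gave 371 (b) in CD8 T-like cells, 200 (b) and 251 (c) in CD4 T-like cells, 1088 (a), 46 (b) and 113 (c) in monocytes and 163 (b) and 175 (c) in Kupffer-like cells. Fits of only the 2 groups gave 0 (b) and 960 (c) in all CD45+ cells, 241 (b) in CD8 T-like cells, 150 (b) and 62 (c) in CD4 T-like cells, 158 (a) and 19 (c) in monocytes and 39 (b) in Kupffer-like cells. Finer clusters gave 33 (b) in CD8 T-like cells, 465 (a) in CD4 T-like cells, 623 (a), 2 (b) and 116 (c) in monocytes, whose class then held monocyte-like clusters only because all 3 clusters closest to macrophages stayed unnamed, and 272 (a) in Kupffer-like cells. At most 5% mitochondrial UMIs gave 74 (b) in all CD45+ cells, 3 (b) in CD8 T-like cells and 328 (a) and 21 (b) in Kupffer-like cells. At least 1000 UMIs gave 68 (b) in all CD45+ cells. Without the cycling cluster CD8 T-like cells gave 83 (b) and 571 (c). With T cells split by UMIs, CD4 T-like cells gave 0 (b), and Asb2 (-0.24), Nr4a2 (0.33), Cxcr3 (-0.13) and Capg (-0.64) reversed (a).

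The replicate number showed no clear pairing, but with so few libraries a shared day or batch could not be excluded. Deviations of 1 of 9 same-numbered pairs correlated above 0.1 (-0.345 to 0.186), and 1 of 9 libraries lay closest to its own number. As a block the replicate number gave 0 (b) and 781 (c) in all CD45+ cells, 903 (c) in CD8 T-like cells, 443 (a), 10 (b) and 32 (c) in CD4 T-like cells and 33 (a), 2 (b) and 3 (c) in monocytes, and 104 list calls with the block in place of 101. It moved no other count by over 1.5 times. Of 251 list tests camera called 101, 0 with an estimated correlation (lowest adjusted p = 0.144), and fry called 58, of which 44 by both.

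Leaving out each library gave these ranges. All CD45+ cells: 3620 to 6386 (a), 0 to 1758 (b), 424 to 1896 (c). CD8 T-like cells: 4062 to 5868 (a), 0 to 806 (b), 45 to 3184 (c). CD4 T-like cells: 204 to 1347 (a), 1 to 166 (b), 41 to 345 (c). Monocytes and macrophages: 4 to 2051 (a), 0 to 3 (b), 0 to 20 (c). Kupffer-like cells: 175 to 770 (a), 18 to 182 (b), 31 to 96 (c). Without 9D9 + epacadostat replicate 2 neutrophils gave 464 (a), 550 (b) and 81 (c) and type 1 dendritic cells 485 (a), 1 (b) and 9 (c), and lists of all CD45+ and Kupffer-like cells gave 35 calls as before. B-like (319, 29, 6), NKT-like (81), nonclassical monocyte (975, 0, 217) and type 2 dendritic cells (767, 1, 36) did not hold that library. Shared calls, where only vehicle libraries were left out, ranged from 0 to 31 in CD8 T-like cells and 0 to 0 in monocytes. For shares the 3-group test passed 0 classes in every alternative. NK-like cells had an adjusted p = 0.05, not under the threshold, with centred log ratios, with at least 1000 UMIs and with named leukocytes as denominator. Pairs and both treatments together gave 0 to 0.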

Other observations

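In nonclassical monocytes anti-4-1BB also raised interferon and MHC class II genes, and in B-like cells it raised interferon genes. Nonclassical monocytes gave 440 higher and 535 lower genes (log2, SE, n = 3 against 3, edgeR), with the chemokine receptor gene Ccr2 at 2.51 ± 0.24, Irf7 at 2.35 ± 0.22 and the interleukin-1 antagonist gene Il1rn at 2.83 ± 0.38. Fabp4 (-2.96 ± 0.35), Apoe (-2.26 ± 0.30) and Cd36 (-1.73 ± 0.21), genes of lipid handling, fell. Type I interferon genes rose in 14 of 21 (camera adjusted p = 5.34e-11; adjusted p = 0.352 with an estimated correlation) and MHC class II genes in 8 of 13 (adjusted p = 3.38e-05; adjusted p = 0.452 with an estimated correlation), and Ifi44 was at least 22.3-fold higher (74 UMIs against 0, floor of 3 over the group). The few remaining B-like cells (31 to 58 barcodes per library) had 167 genes higher and 152 lower, with Gbp2 at 1.82 ± 0.29, Zbp1 at 1.74 ± 0.25 and Ifi27l2a at 1.63 ± 0.17. Their interferon-gamma genes rose in 8 of 21 (adjusted p = 9.26e-06; adjusted p = 0.478 with an estimated correlation), type I genes in 3 of 14 (adjusted p = 5.29e-06; adjusted p = 0.352 with an estimated correlation) and MHC class II genes in 3 of 13 (adjusted p = 0.00583; adjusted p = 0.512 with an estimated correlation). Summed MHC class II genes overlapped between groups in B-like cells. They stood at 42073.9, 40468.1 and 39847 CPM in vehicle libraries and 41494.1, 53998.5 and 47365.9 CPM under anti-4-1BB. In 9D9 + epacadostat replicates 1 and 3 the sums were 53080.9 and 48556.3 CPM. RNA of other cells was higher there too, with Lyz2 at 552 ± 138 CPM (SD, n = 3) against 227 ± 62.2 CPM in vehicle and Nkg7 at 207 ± 112 CPM against 78.0 ± 30.4 CPM. If all Lyz2 came from monocytes and macrophages, a bound computed after the data were seen, they would bring 4.40% to 8.47% of the UMIs of type I genes, 2.50% to 4.83% of interferon-gamma genes and 1.99% to 3.95% of MHC class II genes under anti-4-1BB, and CD8 T-like cells by Nkg7 at most 6.20% of any of these lists. Of 10 B and plasma cell activation genes 1 rose and 1 fell. NKT-like cells (n = 2 against 3) had 23 genes higher and 58 lower. Ifng, the interferon-gamma gene itself, fell there (-1.28 ± 0.23), with Nr4a3 (-3.14 ± 0.54), Nr4a2 (-2.76 ± 0.45) and Klf2 (-1.53 ± 0.26), and stress genes fell in 6 of 19 (adjusted p = 0.00158; adjusted p = 0.352 with an estimated correlation).

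Some interferon-induced genes differed between the treatments in neutrophils, where no list was tested. In neutrophils 9D9 + epacadostat had 263 genes higher and 288 lower than vehicle (log2, SE, n = 3 against 3, edgeR), with the tubulin gene Tubb5 up (3.94 ± 0.60) and Irgm1 (-2.98 ± 0.40) and Rsad2 (-2.68 ± 0.35), interferon-induced genes, down. Against anti-4-1BB Ifit3 (-3.53 ± 0.38), Irgm1 (-3.27 ± 0.39) and Ifi47 (-3.08 ± 0.36) were lower. The makeup of neutrophils differed with the groups. Finer cluster 22 held 84, 98 and 85 barcodes in vehicle libraries, 82, 50 and 21 under anti-4-1BB and 23, 3 and 48 under 9D9 + epacadostat. Finer cluster 32, led by Camp, Ngp and Ltf, held 7, 11 and 0, then 42, 21 and 13, then 48, 2 and 51. How far this makeup carries the called genes was not tested. Anti-4-1BB itself gave 145 genes higher and 164 lower in neutrophils, with Tubb5 at 3.56 ± 0.58 and Ly6a at 2.97 ± 0.37, and 464 genes in place of 309 without 9D9 + epacadostat replicate 2. Type 1 dendritic cells under anti-4-1BB had 117 genes higher and 171 lower (485 in place of 288 without that library), with Serpina3g at 1.96 ± 0.24 and Iigp1 at 1.73 ± 0.28. Type 2 dendritic cells had 294 higher and 473 lower, with Ly6a at 1.86 ± 0.29 and Ifitm1 at 1.75 ± 0.17. Under 9D9 + epacadostat, edgeR called 0 genes against vehicle in type 1 dendritic cells (719 at an unadjusted p under 0.05; 1 without replicate 2), 0 in nonclassical monocytes (375 unadjusted) and 1 in type 2 dendritic cells, and DESeq2 was not run in these classes. Between the treatments edgeR called 4 and 36 genes in type 1 and type 2 dendritic cells, with Irf7 lower under 9D9 + epacadostat in both (-2.04 ± 0.24 and -1.69 ± 0.31).

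Gcg, the glucagon gene, was read in CD8 T-like sums of anti-4-1BB at 50.5 CPM and of vehicle at 2.25 CPM (n = 3 each). It was among the 10 leading genes of CD8 T-like finer cluster 19, which drew 83.1% of its barcodes from 1 library. Anti-4-1BB replicates 1, 2 and 3 held 531, 13 and 9 of these barcodes. How much of the Gcg reading rests on replicate 1 was not tested. Cd79a, a B cell gene, had 13.4 ± 0.247 CPM (SD, n = 3) in vehicle monocytes and macrophages and 1.23 ± 0.222 CPM under anti-4-1BB, along with the lower share of B-like cells.

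Of the tests that follow, the 2 on the spread of markers in 9D9 + epacadostat replicate 2 and the 9 on other splits of the libraries were chosen only after the result was seen. The thinned counts and the cycling cluster were chosen once the data had been seen, and what they should show was written before their own result was. The first pattern is the breadth of the CD8 T-like response to anti-4-1BB, 5521 genes. With every library thinned to the lowest total, 4484 genes were called, and without the cycling cluster 4271, both within 1.5 times, which argues against depth or cycling cells as the whole cause. What stays open is how far other changes in cluster makeup contribute, and the treatment itself was not separated from them.

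The second pattern is the fall of hepatocyte transcripts in CD8 T-like sums under anti-4-1BB, where Alb went from 23.1 ± 1.56 to 4.94 ± 1.54 CPM (SD, n = 3). No member of that list is in another list, and CD45 enrichment should remove hepatocytes. Free hepatocyte RNA may be the source. The list was lower in every anti-4-1BB library than in every vehicle library in 5 of 8 other classes, fewer than the bound set beforehand needed. Hepatocyte fragments on single barcodes stay open too, since the richest 5% of vehicle CD8 T-like barcodes held 39.2% of these UMIs, between the bounds set beforehand, and 26.9% to 31.0% would lie there if spread evenly.

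The third pattern is the mixed profile of 9D9 + epacadostat replicate 2, where cell types were told apart only in part. Finer clusters of its barcodes were led by Gpnmb and Trem2 (689 barcodes), Siglech and Ccr9 (428), Ncr1 and Klra4 (238) and Fscn1 and Ccl22 (188), while those of 4797 and 729 barcodes were led by Notch2 and Abhd2, which mark no cell type of the fixed lists. The clusters of 428 and 238 barcodes were also led by Spry2, as was the largest, and scored closest to CD8 T cells. At 500 UMIs per barcode the variance of lineage marker UMIs was 2.46 times their mean in this library, and 11.8 to 17.7 times in the others. Shallow barcodes of single cells would keep the ratio of the other libraries, of which 11.8 was the lowest, so the values argue against that as the whole explanation. RNA of many cells in every barcode may be the source, but the ratio lay above the bound of 1.5 that was set for it and some clusters were led in part by genes of 1 cell type, so this stays open. No biological explanation was tested.

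Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Each other split also mixes libraries of both groups, so any difference between them widens the spread and lowers its count. The counts below therefore cannot tell treatment from any other difference between the groups. The real split was the only 1 of 10 to give as many genes in all CD45+ cells (5690, 262 and 1773), CD8 T-like cells (5521 for anti-4-1BB), CD4 T-like cells (844 for anti-4-1BB) and monocytes and macrophages (317 for anti-4-1BB), where the highest other split gave 0. In Kupffer-like cells the real counts were 560, 68 and 76 and the highest other splits gave 3, 0 and 9.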
